A study of Rattus norvegicus with 6 samples.

How the data were processed

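Total RNA of 6 samples of rat pluripotent cells from the Sprague-Dawley strain was labelled with biotin and hybridised to Affymetrix 3' expression arrays, 1 array per sample. The samples were 3 of rat embryonic stem (ES) cells and 3 of rat flat pluripotent stem (fPS) cells by sample title and cell type, although the description field of the fPS samples also reads embryonic stem cells. Per the labels' protocols, which are the same for both groups, the cells were grown in a medium with LIF, a GSK3 inhibitor and a MEK inhibitor, and were maintained on feeder cells (mouse embryonic fibroblasts whose division had been blocked) in a medium with serum. They were removed by hand, rinsed and lysed in Trizol. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

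The deposited values are linear intensities, 1 per probe set and array, as their range shows. The method of summarising probes, the background correction and the scaling between arrays are not given in the sources used here. The medians of the 6 arrays ran from 36.2 to 45.3 and the means after trimming 2% at each end from 145 to 199, so the values do not show which scaling was applied. The table held 0 other columns per sample, so no detection calls were at hand. The table held 31099 probe sets, of which 57 were controls and were left out, and 31042 were tested. Gene symbols came from the platform's annotation table: 20826 probe sets had 1 symbol, 436 had several and 9780 had none, and a probe set with several symbols was given no name. The gene identifiers of 20758 probe sets were found in a RefSeq gene table of the rat assembly GRCr8, and 0 symbols changed. That table was used only for names, for the chromosome of a gene and for its neighbours.

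Values were analysed as log2(intensity + 16). A fold change is therefore on that scale, which understates the change of dim probe sets. No further normalization and no filter on dim probe sets were applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all 31042 probe sets and a threshold of 0.05 on the adjusted p. For counts of genes, each of 14217 genes was represented by its probe set with the highest mean over all 6 arrays. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 25 lists, with an estimated correlation and with fry. Fry's directional test asks whether the members of a list move on balance to 1 side, and its mixed test whether they change in either direction. The genes of each chromosome were tested in the same way as a set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

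The groups, tests, gene lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined. The rule for naming genes took the core factors Pou5f1, Sox2 and Nanog, then the 5 genes with the largest rise and the 5 with the largest fall among those past the threshold whose groups did not overlap, with symbols that are not provisional (no LOC or RGD prefix), and then up to 3 members of each list, with fewer for some: those past the threshold with the largest change, filled up with the brightest of the others. Of 458 list members, 379 were measured with a probe set of their own. Pou5f1 and Nanog had no probe set named for them in the annotation table and were not analysed here. Further genes and the 6 gene groups of the closing part, of which the ERK group is a part of the ERK list fixed before, were chosen after their values were seen, and the immediate-early group and the ERK group compared with it were widened after a first version of the test, which had left out members. The list members named in the report outside the rule were also chosen then: Dusp4, Spry1, Tex101, Cdkn1a, Mdm2 and Gadd45a.

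The fit was tested on simulated data with 3 arrays per group, 31042 probe sets, of which 200 were changed, and variances drawn from the distribution that limma fitted to the real arrays. It recovered 5.7% of the probe sets changed by 2-fold, 78.4% of those changed by 4-fold, 96.0% of those changed by 8-fold and 99.2% of those changed by 16-fold, and 5.04% of its calls were false. In 20 runs without any change, 0 runs gave a call. The noise was drawn independently for each probe set, so these rates do not cover variation that probe sets share on the real arrays. Lists of 15 genes shifted by 0.5 on the log2 scale were called in 100% of 40 runs, with members that varied independently of each other. The number of arrays limits the precision of every value.

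The alternatives were quantile normalization, centring of each array on its median, leaving out the dimmest 30% or 50% of probe sets, the trend and robust settings of eBayes, a test against a minimum change of 1.2-fold (treat), a linear model without moderation, the replicate number as a block, the mean over all probe sets of a gene, leaving out probe sets marked as not specific to 1 gene, pseudocounts of 1 and 64, and leaving out each array in turn. Of the 2 alternatives added after seeing the data, one left out the array with the most collagen signal in each group and the other used the mean of 7 collagen genes per array as a covariate.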

Results

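Genome-wide transcript levels were compared between rat embryonic stem (ES) cells and rat flat pluripotent stem (fPS) cells, with 3 arrays in each group. The comparison addresses how the transcripts of fPS cells differ from those of ES cells under protocols that the labels give as the same. The median intensity was 37.6, 38.7 and 37.7 on the ES arrays and 45.3, 39.8 and 36.2 on the fPS arrays. The signal of β-actin probes near the 3' end over those near the 5' end, a measure of RNA integrity and labelling, lay between 2.06 and 4.37, with the highest value on fPS replicate 2, and the same ratio for GAPDH lay between 0.956 and 1.01.

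On average, arrays of the same group resembled each other more than arrays of different groups, while single pairs overlapped. Over all probe sets, Pearson's r of log2 values was on average 0.964 within ES and 0.964 within fPS cells, against 0.946 between them, with ranges of 0.958 to 0.972, 0.956 to 0.970 and 0.932 to 0.961. The highest value between groups, of ES replicate 2 with fPS replicate 1, was 0.9612. It lay above that of fPS replicate 1 with fPS replicate 3 (0.956). Those of ES replicate 3 with ES replicates 1 and 2 were also lower (0.9583 and 0.9606). These correlations are across probe sets, which are not independent replicates. The first principal component held 39.5% of the variance and separated the groups, and the next held 21.8%.

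The strongest rises in fPS cells were in Fos and Jun, the subunits of the AP-1 transcription factor. All 3 fPS arrays lay above all 3 ES arrays for each gene named here as a rise, and below for each fall. The rule for naming these genes required this. Fos went from an intensity of 107 ± 141 (SD, n = 3) to 2155 ± 638, a log2 change of 4.74 (SE 0.686, adjusted p = 0.0354), while the other of its 2 probe sets had the opposite sign. Jun went from 30.5 ± 13.2 to 527 ± 183, a log2 change of 3.53 (SE 0.311, adjusted p = 0.0238). Bhlhe41, a repressor of the circadian clock, Dusp9, a phosphatase that inactivates ERK, and Klf15, a transcription factor of metabolism, rose by 3.15, 3.02 and 2.92. The strongest falls were in Hoxa9, from 341 ± 281 to 3.94 ± 4.08, a log2 change of -3.89 (SE 0.486, adjusted p = 0.0332), and, among others, in its neighbour Hoxa10, with -2.82 (SE 0.365), both genes of body patterning in the HoxA cluster on chromosome 4. Klf3, a transcriptional repressor, B4galt6, an enzyme of glycolipid synthesis, and Trim2, a ubiquitin ligase, had log2 changes of -2.97, -2.75 and -2.67. The probe set for Jun is marked as not specific to 1 gene, and with such probe sets left out its log2 change was 0.99 (adjusted p = 0.108, in a range over the alternatives from 0.000593 to 0.221).

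**Figure D1:**
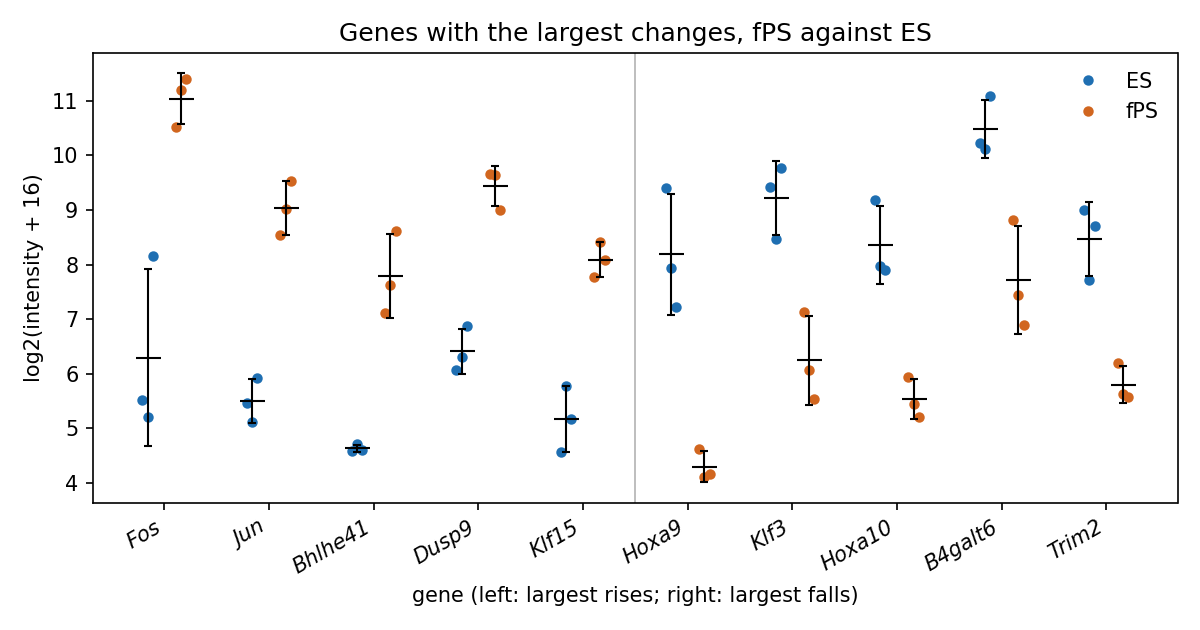
Each point is 1 array, as log2(intensity + 16), for the 5 genes with the largest rise and the 5 with the largest fall in fPS cells, and the black bars give the mean and SD of 3 arrays. All fPS points lie above the ES points for the genes on the left, led by Fos with a log2 change of 4.74, and below them for the genes on the right, led by Hoxa9 with -3.89. The genes were chosen among those whose groups did not overlap.

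In all, 215 of 31042 probe sets passed the limma test, 124 higher and 91 lower in fPS cells, and all 215 differed by at least 2-fold. Counted as genes, 122 of 14217 passed, 81 higher and 41 lower. At an unadjusted p under 0.05 there were 4795 probe sets, where chance would give 1552, and 2484 genes, where chance would give 711. Counts adjusted over a list alone, given below, do not set that list against this background. In 6216 probe sets the groups did not overlap, a share of 20.02% where chance gives 10%. Centring each array on its median gave 376 probe sets, 152 of them higher, and 203 genes, 96 of them higher; the balance of rises and falls thus moved with the scaling. Of the 122 genes, 38 had several probe sets, and in 12 of these at least 1 other probe set had the opposite sign.

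The count of changed genes also rested on single arrays. It was 0 without ES replicate 1, 0 without fPS replicate 2, 1 without ES replicate 3, 3 without fPS replicate 3, 19 without ES replicate 2 and 93 without fPS replicate 1, and with the first 2 of these left out in turn limma still gave 1891 and 1615 genes at an unadjusted p under 0.05. Of the 18 named genes past the threshold, 15 still passed without fPS replicate 1, 7 without ES replicate 2, 2 without fPS replicate 3, 1 without ES replicate 3 and 0 in the other cases. With all arrays and the replicate number as a block, 16 of these 18 passed. All 122 genes kept their sign and an unadjusted p under 0.05 whichever array was left out. That is a weak check, since the genes were selected in the full fit and each of these fits reuses its remaining arrays. With a pseudocount of 1 the count was 0, and 1831 genes had an unadjusted p under 0.05.

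Among the measured markers of pluripotency no gene passed over all probe sets. Of 19 core, 24 naive and 22 primed genes listed, 9, 16 and 17 were measured, and Pou5f1 and Nanog were among those missing. The fit recovered only 5.7% of simulated 2-fold changes, so changes of that size could be missed. Sox2, a core factor of the pluripotent state, had 3770 ± 738 in ES and 1992 ± 787 in fPS cells, a log2 change of -0.97 (SE 0.309) that did not pass (adjusted p = 0.181). Of 9 core pluripotency genes measured, 0 passed over all probe sets, 1 was lower when adjusted over the list alone, and 8 of 9 had a negative sign, among them Rif1 and Sall4 with log2 changes of -0.28 and -0.15. The list was shifted down by camera (median -0.28, adjusted p = 0.0406), which was lost with an estimated correlation (adjusted p = 0.576). That call was also lost without ES replicate 3, fPS replicate 1 or fPS replicate 3 (adjusted p = 0.463, 0.0515 and 0.0565), and without ES replicate 3 and fPS replicate 3 together, where the median was 0.047 (adjusted p = 0.628). It was lost as well after quantile normalization (median -0.16, adjusted p = 0.0624), without the dimmest 30% and 50% of probe sets (adjusted p = 0.0729 and 0.113) and with a pseudocount of 64 (median -0.18, adjusted p = 0.0689). The median was -0.52 without ES replicate 2, -0.082 without ES replicate 3 and -0.17 without fPS replicate 3. Of 16 genes of the naive state, the ground state of ES cells before implantation, 0 passed over all probe sets or adjusted over the list alone. Among them Klf2 had 3657 ± 267 and 3453 ± 957, Klf5 2454 ± 333 and 3056 ± 39.9, and Tfcp2l1 2023 ± 674 and 2056 ± 497 in ES and fPS cells. Of 17 genes of the primed epiblast after implantation, 0 passed over all probe sets and 1 was higher and 1 lower when adjusted over the list alone. Lef1, Enah and Tead2 had log2 changes of -1.67, -0.14 and 0.48 there (adjusted p = 0.0742 for Lef1, and 0.0342 without fPS replicate 1). The naive list (median -0.24, adjusted p = 0.45) and the primed list (median 0.015, adjusted p = 0.948) were not shifted, and without single arrays their medians ran from -0.39 to -0.039 and from -0.14 to 0.25.

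Among 16 feedback and target genes of the ERK pathway, a kinase cascade that the MEK inhibitor of the medium blocks, 4 were higher, 0 lower and 12 did not pass. Adjusted over the list alone, 5 were higher and 1 lower. The 4 were Fos, Egr1, an immediate-early transcription factor with a log2 change of 2.75 (SE 0.306, adjusted p = 0.0284), the ERK phosphatase Dusp4 with 1.35 and the pathway inhibitor Spry1 with 1.32. Of 11 Wnt target genes, 0 passed over all probe sets and 2 were lower when adjusted over the list alone. Lef1, a transcription factor that acts with β-catenin, and Cdx2, a factor of trophectoderm and hindgut, had log2 changes of -1.67 and -1.86 (adjusted p = 0.0742 and 0.0607). Both passed in some alternatives, among them centred arrays (adjusted p = 0.0394 and 0.0371), and Lef1 also without fPS replicate 1 (adjusted p = 0.0342). Over the alternatives the adjusted p ran from 0.0157 to 0.323 for Lef1 and from 0.0109 to 0.312 for Cdx2. By camera the ERK list was shifted up (median 0.070, adjusted p = 0.0447) and the Wnt list down (median -0.33, adjusted p = 0.0406), and both calls were lost with an estimated correlation (adjusted p = 0.389 with an estimated correlation for each). The ERK call was also lost without ES replicate 2, ES replicate 3 or fPS replicate 1 (adjusted p = 0.127, 0.0551 and 0.147) and the Wnt call without ES replicate 3 or fPS replicate 1 (adjusted p = 0.147 and 0.0591). Both were lost without ES replicate 3 and fPS replicate 3 together (adjusted p = 0.0546 for ERK and 0.148 for Wnt). A pseudocount of 64 and the collagen covariate also lost the Wnt call (adjusted p = 0.0689 and 0.0583, median -0.13 with the pseudocount). The ERK call was lost after quantile normalization (adjusted p = 0.0594), without the dimmest 50% of probe sets (median -0.012, adjusted p = 0.113), with the trend and robust settings (adjusted p = 0.0553), the replicate block (adjusted p = 0.0822), the mean over probe sets (adjusted p = 0.0986), pseudocounts of 1 and 64 (medians 0.16 and 0.030, adjusted p = 0.0539 and 0.0689) and the collagen covariate (adjusted p = 0.074). The Wnt median was -0.078 without fPS replicate 3. The ERK median was 0.14, 0.0047 and 0.13 without ES replicates 1, 2 and 3, and -0.081, 0.17 and 0.28 without fPS replicates 1, 2 and 3. Of 13 LIF and STAT3 target genes, 0 passed over all probe sets, and 3 were higher and 1 lower adjusted over the list alone. That list was not shifted (median 0.32, adjusted p = 0.186, and medians from 0.18 without fPS replicate 1 to 0.40 without ES replicate 3), and its members Klf5 and Tfcp2l1 had log2 changes of 0.32 and 0.046.

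Germ cell genes were among those that rose. Of 12 measured, 3 were higher, 0 lower and 9 did not pass, and 4 were higher adjusted over the list alone. Sycp3, a protein of meiotic chromosomes, went from 385 ± 18.4 to 1685 ± 193, a log2 change of 2.08 (SE 0.199, adjusted p = 0.0238). Mov10l1, a helicase of the piRNA pathway, and Tex101, a germ cell surface protein, rose by 1.81 and 1.65. The list was shifted up (median 0.47, adjusted p = 0.000194), which was lost with an estimated correlation (adjusted p = 0.353). Of 24 endoderm genes, 0 passed over all probe sets and 6 were higher adjusted over the list alone, and 19 of 24 had a positive sign. Its brightest members were the laminins Lama1, Lamb1 and Lamc1, with log2 changes of -0.48, 0.86 and 0.51 that did not pass. The endoderm list was shifted up (median 0.58, adjusted p = 3.5e-05), again lost with an estimated correlation (adjusted p = 0.353). Over the alternatives the median ran from 0.36 to 0.78 for germ cell genes and from 0.27 to 0.98 for endoderm genes.

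In the trophectoderm list, 1 of 15 genes was lower, Tfap2a, a transcription factor of surface ectoderm and trophoblast, with a log2 change of -2.30 (SE 0.356, adjusted p = 0.0388). Adjusted over the list alone, 2 were lower. Tfap2c had a log2 change of 0.38 that did not pass. Of 14 neuroectoderm genes 0 passed over all probe sets and 1 was lower adjusted over the list alone, and Sox11 and Tubb3 had log2 changes of -1.21 and -1.05 (adjusted p = 0.0607 and 0.176). Sox11 passed in some alternatives, among them quantile normalization (adjusted p = 0.0476, in a range over the alternatives from 0.0191 to 0.265). Of 12 genes of primitive streak and mesoderm 0 passed over all probe sets, with 1 higher and 2 lower adjusted over the list alone, and Bmp4 and Eomes had log2 changes of -0.43 and -0.31. None of these 3 lists was shifted by camera (adjusted p = 0.446 for trophectoderm, 0.688 for neuroectoderm and 0.967 for streak and mesoderm), whereas fry's mixed test passed for each (adjusted p = 0.00584, 0.0126 and 0.00511). The mixed test does not set a list against other genes, and it passed for 14 of the 25 lists. Since 2484 of all 14217 genes had an unadjusted limma p under 0.05, these passes show no change particular to these lists.

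Of 17 epithelial genes, 1 was higher, the tight junction protein Cldn4, which went from 322 ± 127 to 1615 ± 377, a log2 change of 2.31 (SE 0.310, adjusted p = 0.0332), and 2 were higher adjusted over the list alone. The adhesion protein Epcam was at 3511 ± 542 and 3548 ± 101. The epithelial list was not shifted (median 0.19, adjusted p = 0.135), but it was shifted up without ES replicate 3 (median 0.23, adjusted p = 0.0258, in a range over the alternatives up to 0.688). Without single arrays its median ran from -0.013 (without ES replicate 1) to 0.26 (without fPS replicate 1), neither of which passed. Of 14 genes of the epithelial-mesenchymal transition, 0 passed over all probe sets or adjusted over the list alone, and the list was not shifted (adjusted p = 0.967). Fibronectin (Fn1) had a log2 change of -0.42 and vimentin (Vim) of 1.58 with an SE of 1.06. Of 27 adhesion and actin genes, 0 passed over all probe sets and 2 were higher adjusted over the list alone. Actn1, Vcl and Tagln2 had log2 changes of 0.029, -0.64 and -0.32. That list was shifted up (median 0.13, adjusted p = 0.0494), which was lost with an estimated correlation (adjusted p = 0.576). The call was kept when ES replicate 3 was left out and lost without ES replicates 1 or 2 or fPS replicates 1, 2 or 3 (adjusted p = 0.116, 0.153, 0.0515, 0.0509 and 0.108). It was lost as well after quantile normalization (median 0.22, adjusted p = 0.0524), without the dimmest 30% and 50% of probe sets (adjusted p = 0.0961 and 0.165, median 0.046 for the latter), with the trend and robust settings (adjusted p = 0.0553), with pseudocounts of 1 and 64 (medians 0.30 and 0.088, adjusted p = 0.0604 and 0.0909) and with the collagen covariate (adjusted p = 0.103). Its median was 0.29 without ES replicate 3, 0.28 without unspecific probe sets, 0.34 without ES replicate 3 and fPS replicate 3 together and 0.073 with centred arrays. Each of these settings kept the camera call (adjusted p = 0.0258, 0.0169, 0.0439 and 0.0457).

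Markers of fibroblasts, the feeder cell type, varied within both groups. Of 21 such genes 0 passed over all probe sets or adjusted over the list alone, and the list was not shifted (median 0.23, adjusted p = 0.368). Without ES replicate 3 it was shifted up (median 0.42, adjusted p = 0.0258, in a range over the alternatives up to 0.859), and without ES replicate 1 the median was -0.0098. The mean log2 value of 7 collagen genes was 5.60, 6.33 and 7.67 on the ES arrays and 6.59, 6.31 and 7.47 on the fPS arrays. Col1a2 and Col5a2 had log2 changes of 1.11 (SE 1.14) and 0.61 (SE 1.04), and Timp1 of 0.55 (SE 0.450). With the arrays of highest collagen signal, ES replicate 3 and fPS replicate 3, both left out, 0 genes passed and 2329 had an unadjusted p under 0.05. With the collagen level as a covariate, 61 genes passed, 55 of them among the 122, and Klf3, B4galt6, Trim2, Tfap2a and Tet1 no longer did.

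**Figure D2:**
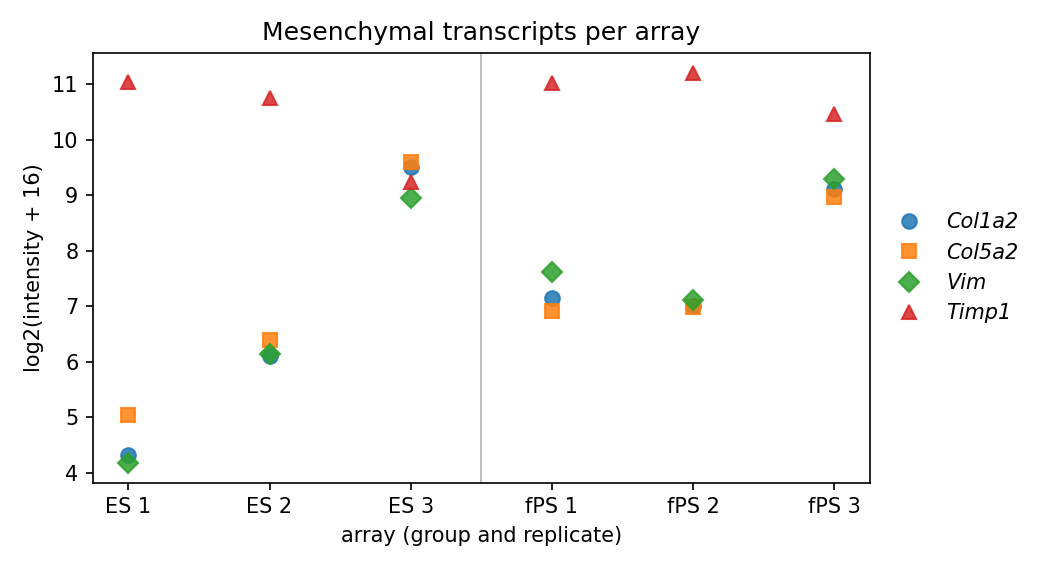
Log2(intensity + 16) of Col1a2, Col5a2, Vim and Timp1 on each of the 6 arrays, 1 symbol per gene and array, with the ES arrays left of the vertical line and the fPS arrays right of it. Within each group the collagens and Vim are highest on replicate 3, where Col1a2 reads 9.51 in ES and 9.12 in fPS cells, and Timp1 is lowest there, at 9.24 and 10.5.

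Targets of p53, the stress-responsive tumour suppressor, had the largest shift of the 25 lists. Of 14 measured, 1 was higher over all probe sets, the kinase Plk2, which went from 130 ± 41.8 to 796 ± 382, a log2 change of 2.41 (SE 0.360, adjusted p = 0.0367). Adjusted over the list alone, 11 were higher and 0 lower. The cell cycle inhibitor Cdkn1a was at 292 ± 56.7 and 603 ± 249, the p53 inhibitor Mdm2 at 843 ± 168 and 1586 ± 259, the stress gene Gadd45a at 140 ± 68.2 and 421 ± 111, and Ccng1 at 1592 ± 573 and 2680 ± 153, none of which passed over all probe sets. The list was shifted up (median 0.93, adjusted p = 1.3e-07), which was lost with an estimated correlation (adjusted p = 0.353). Of 22 cell cycle genes 0 passed over all probe sets or adjusted over the list alone and 19 had a negative sign. Pcna and Ccna2 had log2 changes of -0.35 and -0.20. The list was shifted down (median -0.25, adjusted p = 0.0194), which was lost with an estimated correlation (adjusted p = 0.811). The call was also lost without ES replicate 3 or fPS replicate 3 (adjusted p = 0.248 and 0.196), after quantile normalization (median -0.12, adjusted p = 0.0694) and without the dimmest 50% of probe sets (adjusted p = 0.0873), and with ES replicate 3 and fPS replicate 3 both left out the median was 0.13 (adjusted p = 0.941, in a range over the alternatives from 0.00156 to 0.941). The median was -0.38 without ES replicate 2, -0.028 without ES replicate 3, -0.38 without fPS replicate 2 and -0.074 without fPS replicate 3.

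In the lists of glycolysis, oxidative phosphorylation and cholesterol synthesis, no gene passed over all probe sets. Of 18 glycolysis genes and 28 of oxidative phosphorylation, 0 passed over all probe sets or adjusted over the list alone. Pgk1 and Eno1 had log2 changes of -0.054 and -0.28, and Atp5f1b and Cox6c of -0.12 and 0.12. The glycolysis list was not shifted (median 0.026, adjusted p = 0.491), but it was shifted up without ES replicate 3 and fPS replicate 3 together (median 0.35, adjusted p = 0.0303, in a range over the alternatives up to 0.99), and its median ran from -0.12 to 0.21 without single arrays. The list of oxidative phosphorylation was shifted down (median -0.18, adjusted p = 0.0406), which was lost with an estimated correlation (adjusted p = 0.576) and without ES replicate 1, ES replicate 2 or fPS replicate 1 (adjusted p = 0.216, 0.153 and 0.147). Quantile normalization lost it too (median -0.055, adjusted p = 0.446), as did leaving out the dimmest 30% or 50% of probe sets (adjusted p = 0.0961 and 0.165), the mean over probe sets (adjusted p = 0.0907), leaving out unspecific probe sets (adjusted p = 0.0559) and the collagen covariate (adjusted p = 0.0856). Its median was -0.097 without fPS replicate 3. Of 14 genes of cholesterol synthesis, 0 passed over all probe sets or adjusted over the list alone and 12 had a negative sign. Fdps and Idi1 had log2 changes of -0.41 and -0.062. That list was shifted down (median -0.38, adjusted p = 0.0397), lost with an estimated correlation (adjusted p = 0.811) and without ES replicate 3, fPS replicate 1 or fPS replicate 2 (adjusted p = 0.317, 0.199 and 0.253). The cholesterol call was also lost after quantile normalization (median -0.23, adjusted p = 0.153) and without the dimmest 30% or 50% of probe sets (adjusted p = 0.0659 and 0.113). Its median was -0.14 without ES replicate 3 and -0.22 without fPS replicate 2. Of 17 genes of endoplasmic reticulum stress and heat shock, 0 passed over all probe sets and 2 were higher adjusted over the list alone, and the list was not shifted (adjusted p = 0.967). Atf4 and Hspa5 had log2 changes of -0.34 and 0.39.

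The imprinted non-coding RNA H19 rose from 206 ± 109 to 818 ± 194, a log2 change of 1.99 (SE 0.341, adjusted p = 0.0455), as 1 of 18 imprinted genes. Adjusted over the list alone, 2 were higher and 1 lower, and Gnas had a log2 change of 0.48. The list was shifted up (median 0.47, adjusted p = 0.0264), lost with an estimated correlation (adjusted p = 0.569) and without ES replicate 2 (adjusted p = 0.108) or the dimmest 50% of probe sets (adjusted p = 0.0569). Its median was 0.72 without ES replicate 3. Tet1, an enzyme that oxidises methylated cytosine, fell from 560 ± 161 to 156 ± 62.5, a log2 change of -1.77 (SE 0.310, adjusted p = 0.0489), as 1 of 10 genes of the DNA methylation machinery, all 10 of which had a negative sign. Adjusted over the list alone, 2 were lower, and Uhrf1 had a log2 change of -0.048. That list was shifted down (median -0.24, adjusted p = 0.0187), lost with an estimated correlation (adjusted p = 0.605) and without ES replicate 3 (adjusted p = 0.317) or the dimmest 50% of probe sets (adjusted p = 0.0524). Without ES replicate 3 and fPS replicate 3 together, the median of the DNA methylation list was 0.026 (adjusted p = 0.521). It was -0.64, -0.56 and -0.14 without ES replicates 1, 2 and 3, and -0.37 and -0.38 without fPS replicates 1 and 3. Of 18 genes of the interferon response and antigen presentation, 0 passed over all probe sets and 4 were higher adjusted over the list alone. B2m and Ifitm3 had log2 changes of -0.11 and 0.44. The list was shifted up (median 0.24, adjusted p = 0.0397), lost with an estimated correlation (adjusted p = 0.353) and without ES replicate 2, ES replicate 3 or fPS replicate 1 (adjusted p = 0.066, 0.0937 and 0.0515), or without ES replicate 3 and fPS replicate 3 together (adjusted p = 0.109). Quantile normalization and leaving out the dimmest 50% of probe sets lost it too (adjusted p = 0.0594 and 0.0873, median 0.36 for the latter). Its median was 0.096 without ES replicate 2, 0.12 without fPS replicate 1 and 0.36 without fPS replicate 3. As a check of sex, the Y-linked gene Uty was at 387 ± 134 and 323 ± 71.8 and Xist, the RNA that silences an X chromosome, at 16.6 ± 7.52 and 34.3 ± 5.88 in ES and fPS cells, and 0 of 3 sex-linked genes passed.

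**Figure D3:**
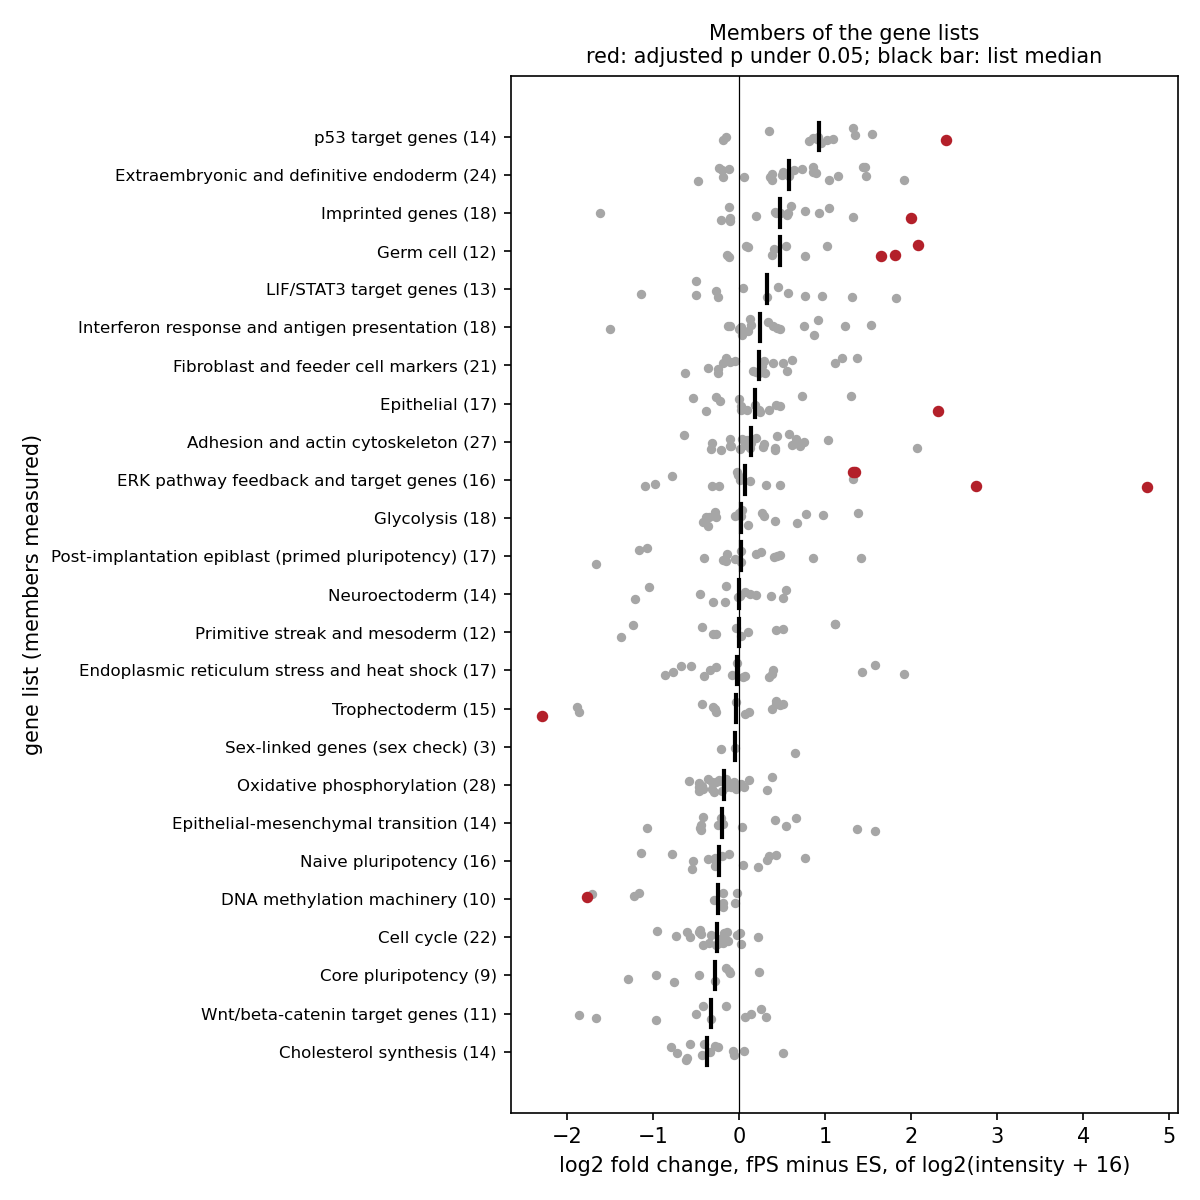
Each point is the log2 change of 1 measured member of a gene list, fPS minus ES, with members past an adjusted p of 0.05 over all probe sets in red and the list's median as a black bar. The median lies furthest to the right for the 14 p53 targets, at 0.93, and furthest to the left for the 14 genes of cholesterol synthesis, at -0.38.

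By camera with the preset correlation, 13 of the 25 lists passed. With an estimated correlation 0 passed and 1 had an unadjusted p under 0.05, fry's directional test gave 0 and 6, and fry's mixed test passed for 14 lists. The lists of p53 targets, germ cells and endoderm passed in 18 of 20 alternatives each, with adjusted p ranging from 1.3e-08, 1.7e-05 and 7.5e-07 to 0.353. The other 10 passed in 6 to 16 of 20. After quantile normalization 6 lists passed, and 4 without the dimmest 50% of probe sets. Of the 25 lists, 11 passed without ES replicate 1, 8 without ES replicate 2, 8 without ES replicate 3, 6 without fPS replicate 1, 11 without fPS replicate 2 and 10 without fPS replicate 3. Median, mean and direction of the test differed in sign for the lists of the primed epiblast (median 0.015, mean -0.043, test up), neuroectoderm (median 0.00099, mean -0.11, test down), the epithelial-mesenchymal transition (median -0.20, mean 0.080, test up), endoplasmic reticulum stress (median -0.021, mean 0.13, test down) and sex-linked genes (median -0.051, mean 0.13, test up). The genes of 22 chromosomes were also tested as sets. By camera 0 were shifted, 0 had an unadjusted p under 0.05, and 0 passed with an estimated correlation.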

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

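The tests of this part on the control probe set and on other splits for probe sets and genes were chosen after the result was seen.

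A control probe set for 5S ribosomal RNA, which enters no comparison of the report, was higher in all 3 fPS than in all 3 ES arrays. Its intensity was 66.8, 91.5 and 97.1 in ES and 141, 181 and 457 in fPS cells, a ratio of mean intensities of 3.05, with an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. It was the 1 control of 57 with all fPS above all ES arrays and at least a 2-fold difference, while 2 controls had all fPS above and 5 all fPS below the ES arrays. Among the latter, a probe set for the middle of hexokinase had a ratio of 0.494 (31.5, 34.1 and 42.1 in ES, 18.7, 18.4 and 16.1 in fPS cells). No explanation was tested.

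The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, there were 215 changed probe sets and 122 changed genes, and the highest count of another split was 0 for both. Each other split mixes ES and fPS arrays, so a difference between the groups adds to its spread, and its count does not measure chance. For gene lists, 1 of the 10 splits reached the real count of 13, and the other counts ran from 2 to 10. Camera with the preset correlation thus called lists in every split. For chromosomes all 10 splits gave 0, as the real one did.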

How the results depend on the processing

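The settings without the high-collagen arrays and with the collagen covariate were chosen after the data were seen, and the others before. The 122 changed genes became 203 with centred arrays (121 shared), 416 and 506 without the dimmest 30% and 50% of probe sets (120 and 102 shared), 358 with the trend and robust settings (121 shared), 300 with the mean over probe sets, 64 with the replicate block (56 shared), 61 with the collagen covariate (55 shared), 26 with a pseudocount of 64 (23 shared) and 13 with a minimum change of 1.2-fold. They became 0 in the linear model without moderation (1958 genes at an unadjusted p under 0.05), with a pseudocount of 1 (1831) and without both high-collagen arrays (2329). The 215 probe sets became 337 after quantile normalization, 376, 759, 899 and 619 in the first settings above in that order, 107 with the block, 95 with the covariate, 41 with a pseudocount of 64, 14 with a minimum change, 1 without moderation and 0 with a pseudocount of 1 and without both high-collagen arrays. Without single arrays the counts ran from 0 to 162 probe sets, 0 to 93 genes and 6 to 11 lists. The 13 shifted lists became 6 after quantile normalization, 4 without the dimmest 50%, 8 without both high-collagen arrays and 0 with an estimated correlation or fry. The difference between mean correlations within and between groups was 0.0174, and 0.0274 and 0.0395 without the dimmest 30% and 50%. No chromosome was shifted in any setting run, 0 by camera. Filters leave fewer probe sets to adjust over and left-out arrays fewer samples; the cause of the other changes was not tested. The labels do not say whether the numbers pair the samples: correlations of deviations from the group mean were 0.15, 0.020 and 0.075 for equal numbers and ran from -0.14 to 0.054 for the others, which shows no strong pairing and does not exclude one. The second principal component fell with the replicate number in both groups. It was 38.1, 22.8 and -55.8 on the ES arrays and 21.0, -0.12 and -26.0 on the fPS arrays. Collagen signal was also highest on replicate 3 in both, so a pairing or a shared batch stays open, untested. Probe sets near the array floor limit what can be seen, since the pseudocount sets their fold.

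Of 1736 alternative values of lists and named genes, 85 changed direction (the sign of a gene's change or the direction of a list's test) with neither value past the threshold and 1, the cell cycle list without both high-collagen arrays, with the report's value past it. The median had another sign in 42 further cases while the direction of the test was kept, among them core pluripotency and DNA methylation without both high-collagen arrays (0.047 and 0.026) and ERK without the dimmest 50% (-0.012) and without fPS replicate 1 (-0.081). The values that changed direction are given as log2 changes of genes and medians of lists, whose sign can differ from that of the test, and the cause was not tested. After quantile normalization they were -0.015 for the primed epiblast, -0.19 for the epithelial-mesenchymal transition, 0.099 for endoplasmic reticulum stress, 0.042 for B2m, 0.079 for Idi1, 0.045 for Klf2, 0.056 for Pgk1, 0.077 for Uhrf1. With centred arrays they were -0.081 for endoplasmic reticulum stress, -0.032 for Actn1, -0.035 for Epcam, -0.014 for Tfcp2l1. Without the dimmest 30% they were -0.092 for the primed epiblast, -0.021 for endoplasmic reticulum stress. Without the dimmest 50% they were -0.16 for the primed epiblast, -0.021 for endoplasmic reticulum stress. With the replicate block they were -0.021 for endoplasmic reticulum stress. With a pseudocount of 1 they were 0.097 for streak and mesoderm. With a pseudocount of 64 they were -0.097 for the epithelial-mesenchymal transition. Without both high-collagen arrays they were 0.049 for naive pluripotency, -0.077 for the epithelial-mesenchymal transition, 0.13 for the cell cycle, 0.072 for Atp5f1b, 0.30 for Ccna2, -0.0029 for Cox6c, 0.27 for Enah, 0.63 for Eomes, 0.11 for Idi1, 0.13 for Klf2, 0.16 for Pgk1, 0.12 for Rif1, 0.28 for Sall4, 0.18 for Uhrf1, 0.14 for Uty. With the collagen covariate they were -0.068 for the primed epiblast, 0.057 for streak and mesoderm, -0.23 for the epithelial-mesenchymal transition, -0.0099 for Actn1, 0.027 for B2m, -0.0070 for Epcam, -0.0079 for Tfcp2l1. By fry they were -0.021 for endoplasmic reticulum stress. With the mean over probe sets they were 0.092 for Pgk1. Without unspecific probe sets they were -0.073 for Gnas. With single arrays left out they ran from -0.14 to 0.25 for the primed epiblast, -0.11 to 0.10 for streak and mesoderm, -0.20 to -0.0065 for the epithelial-mesenchymal transition, -0.12 to 0.21 for glycolysis, -0.21 to 0.084 for endoplasmic reticulum stress, -0.15 to 0.057 for sex-linked genes, -0.39 to -0.039 for naive pluripotency, -0.0098 to 0.42 for fibroblast markers, -0.092 to 0.17 for Actn1, -0.38 to 0.17 for B2m, -0.049 to 2.54 for Col1a2, -0.38 to 1.91 for Col5a2, -0.036 to 0.15 for Epcam. They also ran from -0.14 to 0.30 for Tfcp2l1, -0.21 to 0.0044 for Atp5f1b, -0.0067 to 0.19 for Cox6c, -0.37 to 0.25 for Enah, -0.67 to 0.25 for Eomes, -0.20 to 0.093 for Idi1, -0.13 to 0.079 for Pgk1, -0.37 to 0.15 for Sall4, -0.0010 to 0.90 for Timp1, -0.18 to 0.16 for Uhrf1, -0.49 to 0.016 for Uty, -0.37 to 0.12 for Ccna2, -0.31 to 0.093 for Klf2.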

Other observations

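The gene groups of this part and its tests were chosen after the values were seen, except the test of all 20 genes beside the HoxA cluster, and each pattern is a hypothesis.

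Of 22 measured genes of serine synthesis and targets of ATF4, the transcription factor of the amino acid response, 2 were lower in fPS cells and 20 did not pass over all probe sets. A negative sign was found in 20 of the 22, and the median was -0.81. Phgdh, the entry enzyme of serine synthesis, had a log2 change of -1.86 (SE 0.327, adjusted p = 0.0489), and Slc1a4, a transporter of neutral amino acids, of -1.94 (SE 0.320, adjusted p = 0.0416). Psat1 and Psph, the next enzymes of the pathway, had log2 changes of -1.18 and -1.10 (adjusted p = 0.055 and 0.0714), while Ddit3 and Ddit4, members of the same group, had 1.91 and 1.04. Camera gave an adjusted p of 4.7e-08 over the 6 groups, and 0.0753 with an estimated correlation. The mean of the 20 members that did not pass differed by -0.53 (SE 0.0780), but the group was put together after its values were seen, so this does not test a lower amino acid response, which stays open.

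Of 19 glucocorticoid-responsive genes, 3 were higher: Klf15, Tsc22d3 with a log2 change of 1.88 (SE 0.314, adjusted p = 0.0428) and the phosphatase Dusp1 with 2.32 (SE 0.277, adjusted p = 0.0321). The group was shifted up by camera (adjusted p = 0.00213, and 0.104 with an estimated correlation). Sgk1, Per1 and Fkbp5, classical members, had log2 changes of -1.44, -0.30 and -0.18. The mean of the 16 members past no threshold differed by 0.22 (SE 0.165), within the spread between arrays, and since this group too was put together after its values were seen, a glucocorticoid-like response stays open.

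Of 41 measured immediate-early genes, which are transcribed within minutes of a stimulus, 10 were higher in fPS cells, 0 were lower and the others did not pass, with a positive sign in 31, a negative sign in 10 and a median of 0.46. The mean, which the largest changes (Fos and Jun) pull above the median, differed by 0.87 (SE 0.0927, exact permutation p = 0.1, the smallest possible). As given above, Jun did not pass with unspecific probe sets left out, and the other probe set of Fos had the opposite sign. Camera gave an adjusted p of 5.7e-10, and 0.032 with an estimated correlation. The group was put together after its values were seen and was then widened, so these p-values do not test it. The tables argue against array scaling, since the difference was 0.91 (SE 0.105) after quantile normalization. With the collagen level as a covariate the difference was 0.85 (SE 0.0552). The collagen level itself differed by only 0.26 (SE 0.699) between the groups and was not shown to measure feeder RNA. That covariate could therefore move the difference little, and RNA of feeder cells stays open. Sustained ERK signalling cannot be told apart: 10 ERK pathway genes that are not immediate-early differed by -0.039 (SE 0.210) on average, but Dusp4 and Spry1 were higher while Etv5 and Etv4 had log2 changes of -1.09 and -0.97. A stimulus during picking and rinsing, and a property of fPS cells as such, go with the groups in this design and stay open, untested.

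Of 6 measured HoxA genes, Hoxa9 and Hoxa10 were lower in fPS cells and the others did not pass. All 6 had a negative sign, while Hoxa3l1, named for the cluster but counted among its neighbours, had a log2 change of 0.52. The mean of the 6 differed by -1.99 (SE 0.511). Camera gave an adjusted p of 2.3e-07, and 0.104 with an estimated correlation. This group too was put together after its values were seen, so these p-values do not test it. The tables argue against a loss on both sides of the cluster that lowers the neighbours on average at least 0.5 times as much. The 20 measured genes next to the cluster differed by -0.0063 (SE 0.134), and the 11 of them above the median ES signal by -0.17 (SE 0.169). On 1 side, Pals2, Osbpl3, Hnrnpa2b1, Snx10 and Skap2 had log2 changes of -0.68, -0.74, -0.66, -0.62 and -0.27, none past the threshold. Fam221a, Npy, Spmip4, Npvf and Hoxa3l1 on that side had a positive sign. A mean over both sides cannot show a loss on 1 side, which stays open, untested. These neighbours cannot show a loss confined to the cluster, which stays open, untested. With the collagen level as a covariate the HoxA difference was -1.86 (SE 0.437). Hoxa9 and Hoxa10 still passed the limma test, narrowly (adjusted p = 0.0492 for both, in a range over the alternatives from 0.00132 to 0.25 for Hoxa9). The difference did not exceed 0.5 times the uncorrected one by 2 SE, as first asked. It met only a criterion widened after the value was seen. The HoxA mean had a slope of -0.50 (SE 0.307) on the collagen level, within 2 SE of 0. The collagen level differed by only 0.26 (SE 0.699) between the groups and was not shown to measure feeder RNA. RNA of feeder cells therefore stays open. A change of all Hox clusters cannot be told apart. The 17 genes of the HoxB, HoxC and HoxD clusters differed by 0.21 (SE 0.102), but only 3 of the 17 lay above the median ES signal. Those 3 showed no fall on average, with a difference of 0.375 (SE 0.198), while the others had little room to be lower. A difference between the cell lines also stays open, untested.

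Collagen genes differed within both groups. In the array with most collagen signal of each group, the 7 collagens were on average higher than in the other arrays of that group by 1.36 on the log2 scale. That array was picked by the mean of these same 7 genes, so the sign of this average was fixed in advance. The difference was positive in 6 of the 7 and ran from -0.60 for Col6a2 to 3.17 for Col1a2. The tables argue against array scaling, since the median of all 31042 probe sets differed by -0.049. The remaining 14 fibroblast markers were higher by 0.37 (SE 0.177), 11 of 14 with a positive sign, where the SE is over genes that vary together, but by 0.25 (SE 0.149) without Dcn and 0.48 (SE 0.143) without Timp1, whose own difference was -1.16, so RNA of feeder cells cannot be told apart. How mouse RNA hybridises to these rat probes was not tested, and cells that differentiated in the culture stay open as another source, untested.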
